A study of Danio rerio with 6 samples.

How the data were processed

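Germ cells carrying a foxl2l:egfp reporter were isolated from dissociated trunks of TL-strain zebrafish at 21 days post fertilization, and about 300 EGFP-positive cells per library were collected by fluorescence-activated cell sorting, per the labels' protocols. Full-length cDNA was amplified with the SMART-Seq HT kit and fragmented into libraries with Nextera XT, a chemistry that does not record the strand of the transcript. The 6 libraries fell into 2 genotypes of 3 libraries each, foxl2l-/- and foxl2l+/+. The labels do not say whether the libraries of a genotype came from separate animals or clutches, so the p-values measure the spread between these libraries, which may be partly technical.

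The authors deposited a table with 31743 genes on chromosomes 1 to 25 and the mitochondrial chromosome, with Ensembl identifiers and gene names. Per the file headers, it holds the total count of reads per gene and library, which are raw and not normalised, and TPM values, which the authors scaled by gene length and depth. It also holds the authors' comparison of the genotypes as a log2 fold change and an FDR-adjusted p-value. Genome build GRCz11 and bcl2fastq are named per the submitters' processing notes, while the aligner, the counting program, the annotation release and the model behind the authors' comparison are not given in the sources used here. The handling of reads that match several genes is therefore unknown, and values of near-identical neighbouring genes (the zp2 and zp3 egg coat genes, sult1st7 and sult1st9, cyp46a1.2 and cyp46a1.4) are uncertain because reads could be split between copies. The same holds for genes that overlap on opposite strands. Another 12 columns, RPKM and CPM values per library, were not used here. Of the identifiers, 28988 (91.3%) had a symbol in the reference name table. That table gives foxl2l for the gene the file lists as zgc:194189.

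Counts summed to 25176401 to 39189535 per library. The 3215 genes at 0 in all libraries carried no fold change in the authors' deposited table. Amplified reads without molecular identifiers are not independent molecules, so a total of reads overstates the number of molecules sampled from about 300 cells. Pairs of libraries of a genotype differed by more than repeated sequencing of 1 amplified library would leave, with chi-square per degree of freedom from 33.17 to 120.9. This does not show that the cells were independent. Each library was counted as a replicate as its labels list it.

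The genotypes were compared with edgeR 4.0.16 in R 4.3.3. Genes passing filterByExpr were kept (23576), scaled by TMM and fitted with glmQLFit, and the genotype coefficient was tested with glmQLFTest and Benjamini-Hochberg adjustment at 0.05. Fold changes are log2 of foxl2l-/- over foxl2l+/+, with standard errors from the same fit. CPM values are counts scaled to the TMM-adjusted library total. The 16 gene lists, the rule for named genes, the design and the alternatives were fixed before the data were examined. Lists were tested with camera from limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 16 lists. Camera compares the members of a list with all other genes. Beside it stand camera with an estimated correlation, fry, and counts of members adjusted over the list alone. Measures of library composition were compared with an exact two-sided permutation test, whose smallest possible p with 3 against 3 libraries is 0.1. Counts were simulated for 23094 genes with the means and dispersions of this comparison, 200 of them changed. The same steps recovered 21% of genes changed 2-fold and 77% of genes changed 4-fold, and called 4 of 22894 unchanged genes. The changed share was far below the share called in the data, so the adjusted threshold was stricter. These recoveries therefore do not measure those in the data.

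Named genes are foxl2l, then the 10 highest and 10 lowest fold changes among called genes whose 3 foxl2l-/- libraries all lie above or all below the 3 foxl2l+/+ libraries, with a mean of at least 10 CPM in the higher genotype and a gene name that is not a clone name, then up to 4 members with the smallest p from each list. This rule passed over 9 clone-named genes among the highest and 20 among the lowest. Any gene named outside the rule was chosen after its values were seen, which is said where it appears. Some single-gene results are not reported here. Alternatives were RLE and TMMwsp factors, library totals alone, DESeq2 1.42.0, limma-voom with quality weights, limma-trend on log2(TPM + 1), no low-count filter, a filter of 10 counts in 3 libraries, a 2-fold limit, a prior count of 0.5, the replicate number as a block, and each library left out in turn. Thinning of counts to 25176401 per library was added after the data were seen.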

Results

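Transcript levels were measured by RNA sequencing in EGFP-positive germ cells sorted from juvenile zebrafish at 21 days post fertilization. The reporter marks cells in which the foxl2l promoter is active. Foxl2l encodes a forkhead transcription factor expressed in germ cells, and the series asks how it acts on the entry of juvenile germ cells into female meiosis. The 3 foxl2l-/- libraries held 38405954, 38342961 and 36292276 counts, and the 3 foxl2l+/+ libraries held 37221115, 39189535 and 25176401. At least 1 count was found for 26589 ± 558 genes in foxl2l-/- and 26395 ± 420 in foxl2l+/+ libraries (SD, n = 3 each).

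Reads were assigned to the targeted gene in both genotypes. The foxl2l gene, listed as zgc:194189 (ENSDARG00000008010), spans 29823286 to 29824146 on the reverse strand of chromosome 23 in GRCz11. It received 17736, 22491 and 17630 counts in foxl2l+/+ replicates 1 to 3 and 47231, 40067 and 31437 in foxl2l-/- replicates 1 to 3. Its level was 627 ± 120 CPM in foxl2l+/+ and 978 ± 189 CPM in foxl2l-/- libraries (SD, n = 3). The log2 fold change was 0.64 ± 0.20 (SE), with an adjusted p of 0.0263 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. All foxl2l-/- libraries lay above all foxl2l+/+ libraries, which gives p = 0.1 in a two-sided exact permutation test, the smallest that 3 against 3 allows. The authors' deposited table gives a log2 fold change of 0.67 for this gene. The call ended when foxl2l+/+ replicate 1, foxl2l+/+ replicate 2, foxl2l-/- replicate 1 or foxl2l-/- replicate 2 was left out, with adjusted p of 0.105, 0.0738, 0.0896 and 0.0504 in the same edgeR quasi-likelihood test (0.00206 to 0.105 over the alternatives that repeat a test, leaving aside the 2-fold limit). The labels state neither which part of the gene the mutation alters nor whether the reporter carries foxl2l sequence, so the level of this transcript does not check the genotype labels.

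In the libraries labelled foxl2l-/-, most oocyte and meiotic prophase transcripts tested were lower, while genes of undifferentiated germ cells went both ways, with 10 of 28 higher and 5 lower. The oocyte transcription factor figla, which activates egg coat genes, fell from 296 ± 41.3 CPM in foxl2l+/+ to 1.66 ± 0.896 CPM in foxl2l-/- cells (SD, n = 3). Of the 47 oocyte genes tested 36 fell, and of the 39 meiotic prophase genes 23 fell. The germline stem cell marker nanos2 rose from 0.926 ± 0.0369 to 8.92 ± 2.76 CPM, and id1, an inhibitor of basic helix-loop-helix factors, rose from 3.97 ± 1.23 to 61.6 ± 7.38 CPM. The germ cell marker ddx4, at 1901 ± 167 CPM in foxl2l-/- and 2422 ± 292 CPM in foxl2l+/+ cells, did not pass the test and was chosen after its values were seen.

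**Figure D1:**
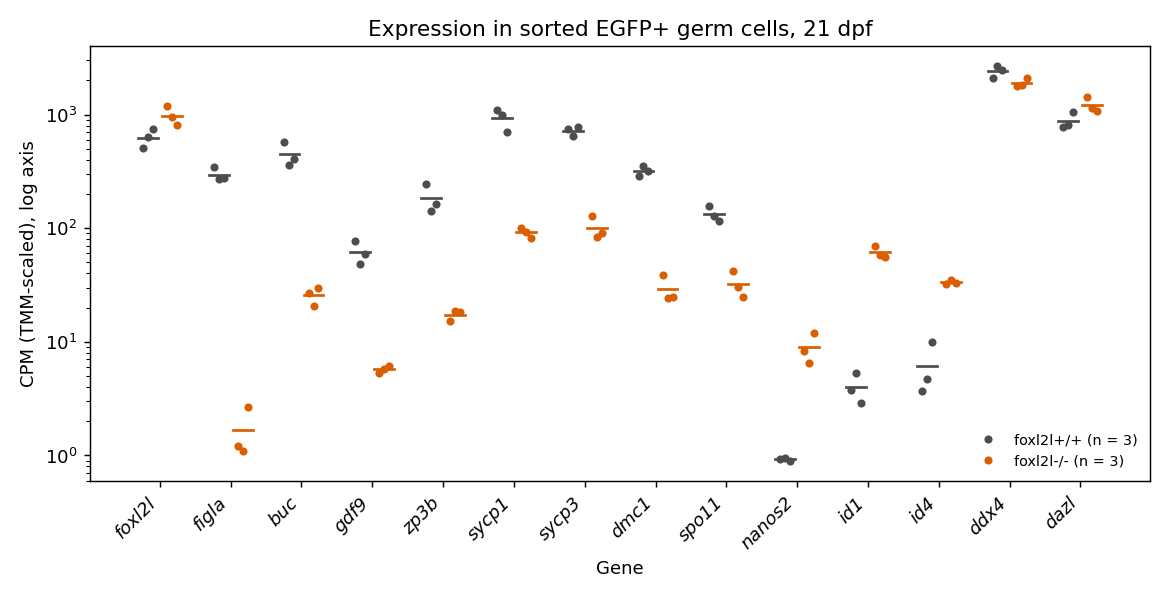
Expression of 14 genes in each library, in TMM-scaled CPM on a log axis, with foxl2l+/+ libraries in grey, foxl2l-/- libraries in orange and a horizontal bar at each genotype's mean (n = 3). The genes were picked after their values were seen to show the main groups: foxl2l stands at the left, figla, buc, gdf9, zp3b, sycp1, sycp3, dmc1 and spo11 lie lower in every foxl2l-/- library, nanos2, id1 and id4 lie higher, and ddx4 and dazl did not pass the test.

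Across the transcriptome, 7443 of 23576 tested genes differed between the genotypes, 3710 higher and 3733 lower in foxl2l-/- cells. Changes of at least 2-fold made up 2912 of the higher and 2489 of the lower calls, and changes of at least 8-fold made up 340 and 387. Over all tested genes, called or not, the 3 foxl2l-/- libraries lay entirely above or entirely below the 3 foxl2l+/+ libraries in 11001 (46.7%), an arrangement that chance gives for 10%. With library totals in place of TMM scaling, 4882 genes were higher and 2723 lower, and the median log2 fold change of all genes moved from 0.048 to 0.252. The authors' deposited table lists 4294 genes higher and 3791 lower at an adjusted p below 0.05, and 7228 (97.1%) of the genes called here are called there in the same direction. The first principal component of log2 CPM held 59.03% of the variance and separated the genotypes. Libraries correlated at 0.9507 to 0.9538 within foxl2l+/+ and at 0.9441 to 0.9692 within foxl2l-/-, against 0.8617 to 0.8917 between genotypes. Replicate 3 of foxl2l-/- stood farthest from its group, at 0.9441 and 0.9524 with the other foxl2l-/- libraries.

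Figla and zglp1 were among the 10 named genes with the lowest fold changes. The sulfotransferase genes sult1st9 and sult1st7, neighbours on chromosome 8 that could share reads, fell by 7.77 ± 0.45 and 6.88 ± 0.59 on the log2 scale (SE). Figla (chromosome 5, 13839316 to 13848296, reverse strand) fell by 7.48 ± 0.36, with an adjusted p of 1.77e-07 in edgeR's quasi-likelihood test. The GATA-type zinc finger gene zglp1, a regulator of the oogenic programme in mice, fell by 6.45 ± 0.28, from 209 ± 24.3 to 2.39 ± 0.804 CPM. The RNA-binding protein gene larp6b fell by 6.24 ± 0.28 and the maternal linker histone gene h1m by 5.90 ± 0.34. Retsatl, named for similarity to retinol saturase, fell by 5.92 ± 0.45, the claudin gene cldnd fell by 5.79 ± 0.35 and the phosducin gene pdca fell by 6.75 ± 0.70. The egg coat gene zp3a.1 fell by 5.55 ± 0.77, with a wide spread of 40.9 ± 42.0 CPM among foxl2l+/+ libraries.

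Pdyn, vox, id1 and bmp2b were among the 10 named genes with the highest fold changes. Pdyn, which encodes the opioid precursor prodynorphin, rose by 6.71 ± 0.58 on the log2 scale (SE), from 0.127 ± 0.0922 to 12.8 ± 4.10 CPM. The homeobox repressor vox, a BMP-responsive gene of the ventral embryo, rose by 4.33 ± 0.30, from 3.31 ± 1.08 to 66.1 ± 14.3 CPM. The ligand gene bmp2b rose by 3.94 ± 0.38 and id1, a known BMP target (chromosome 11, 18704191 to 18705303, reverse strand), by 3.95 ± 0.28, with an adjusted p of 1.77e-06 in edgeR's quasi-likelihood test. The cholesterol hydroxylase genes cyp46a1.4 and cyp46a1.2, adjacent on chromosome 20, rose by 4.26 ± 0.55 and 3.86 ± 0.42. Serpinf1 rose by 4.30 ± 0.57, sowahd by 4.01 ± 0.52 and ccdc87 by 3.96 ± 0.69. The myosin light chain kinase gene mylkb, with a log2 fold change of 5.06 ± 1.23, rested on foxl2l-/- replicate 1, which held 1200 counts against 51 and 29 in the other foxl2l-/- libraries. Without that library its log2 fold change was 1.60, with an adjusted p of 0.215 in edgeR's quasi-likelihood test (0.00227 to 0.215 over the alternatives tried). With all libraries kept, its call also ended under limma-voom with quality weights (3.01, adjusted p = 0.153) and limma-trend on TPM (1.53, adjusted p = 0.127).

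Among the 47 oocyte differentiation and egg coat genes, 36 fell, 2 rose and 9 did not pass, with the same counts adjusted over the list alone and a median log2 fold change of -2.84. The RNA-binding protein gene rbpms2b fell by 4.37 ± 0.21 on the log2 scale (SE), from 352 to 17.0 CPM. The Balbiani body organiser buc fell by 4.11 ± 0.24, from 447 to 25.9 CPM, and the maternal dorsal determinant hwa, listed as si:dkey-121h17.7, by 3.83 ± 0.22. Other members, picked after their values were seen, included the transcription factor lhx8a (-3.53), the growth factor gdf9 (-3.42), the egg coat gene zp3b (-3.40) and the nucleoplasmin npm2b (-3.58). Many of the 36 are zp2 and zp3 egg coat genes, which could share reads and need not count separately. Among these, chosen likewise, zp2.2 (48.5 ± 40.9 CPM) and zp3a.2 (57.7 ± 64.9 CPM) varied widely in foxl2l+/+ libraries (SD), whereas zp3d.1 (131 ± 0.28 CPM) did not. The 2 members that rose were padi2 (1.07) and lhx8b (1.1). Levels of bmp15, wee2 and ybx1, chosen likewise, did not pass, with log2 fold changes of -0.18, -0.36 and -0.36. The camera adjusted p was 5.38e-16, against an adjusted p of 0.373 with an estimated correlation, and fry gave 0.00163. The list took 0.173 ± 0.0067% of counts in foxl2l-/- and 0.518 ± 0.107% in foxl2l+/+ libraries.

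Of the 39 genes for the meiotic chromosome axis, synapsis and recombination, 23 fell, 1 rose and 15 did not pass, and adjusted over the list alone 24 fell and 2 rose. The median log2 fold change was -1.44. Meiob, a single-strand DNA-binding factor of meiotic recombination, fell by 4.13 ± 0.22 on the log2 scale (SE), from 341 to 19.5 CPM. The meiotic cohesin gene rad21l1 fell by 3.08 ± 0.17, the crossover gene msh4 fell by 3.18 ± 0.20 and the synaptonemal complex gene sycp1 fell by 3.34 ± 0.21. Also lower were dmc1 (-3.45), sycp3 (-2.83) and spo11 (-2.04), which were chosen after their values were seen. Hormad1 (-0.23), trip13 (-0.07), mei4 (0.15) and smc1b (-0.51), chosen likewise, did not pass. The camera adjusted p was 7.59e-09, against an adjusted p of 0.337 with an estimated correlation, and fry gave 0.000685.

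The 28 genes of germline stem cells and undifferentiated germ cells went both ways, with 10 rising, 5 falling and 13 not passing, and 11 and 5 adjusted over the list alone. Besides id1, nanos2 rose by 3.26 ± 0.40 on the log2 scale (SE) and id2b by 1.78 ± 0.24, and among members chosen after their values were seen, id4 rose by 2.45, id3 by 1.79 and the GDNF co-receptor gene gfra1b by 2.53. The pluripotency factor gene nanog fell by 1.61 ± 0.23, and pou5f3 and zbtb16a, chosen likewise, fell by 1.63 and 1.25. The median was 0.51, and the list as a whole was not called by camera (adjusted p = 0.388).

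Of the 23 germ cell identity and piRNA pathway genes, 17 did not pass. There 5 fell and 1 rose, likewise adjusted over the list alone, with a median of -0.21 that became 0.00 under library totals, where 4 rose and 3 fell. Without foxl2l-/- replicate 3, 3 rose and 6 fell, with a median of -0.26. Ca15b fell by 3.2 ± 0.43 on the log2 scale (SE), the Tudor domain gene tdrd12 by 1.56 ± 0.29 and tdrkh by 0.72 ± 0.17, whereas nanos3 rose by 1.01 ± 0.28. Nanos3 was the only member that rose in the main fit. With edgeR's quasi-likelihood test its call ended without foxl2l-/- replicate 2 (adjusted p = 0.0661) and without foxl2l+/+ replicate 3 (adjusted p = 0.0587). Its adjusted p ranged from 0.00192 to 0.0661 over the alternatives other than the 2-fold limit. That of tdrkh ended in the same test without foxl2l-/- replicate 2 (adjusted p = 0.0514) and with limma-trend on TPM (adjusted p = 0.066), in a range of 0.000407 to 0.066 over the same alternatives. The germ cell genes piwil1 (-0.21), dazl (0.46) and ddx4 (-0.35), chosen after their values were seen, did not pass. The camera adjusted p was 0.449. Of 35 spermatogenic and sperm genes, 10 fell and 4 rose (11 and 4 adjusted over the list alone; 10 and 7 under library totals), with a median of -0.38 (-0.18 under library totals) and a camera adjusted p of 0.21. The gamete fusion gene izumo1 fell by 2.99 ± 0.30, odf3l2a by 1.86 ± 0.19, odf3b by 2.18 ± 0.28 and the ciliary gene hydin by 2.08 ± 0.31. The male differentiation factor dmrt1, chosen after its values were seen, rose by 0.71 ± 0.16, from 181 ± 10.5 to 295 ± 7.94 CPM.

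**Figure D2:**
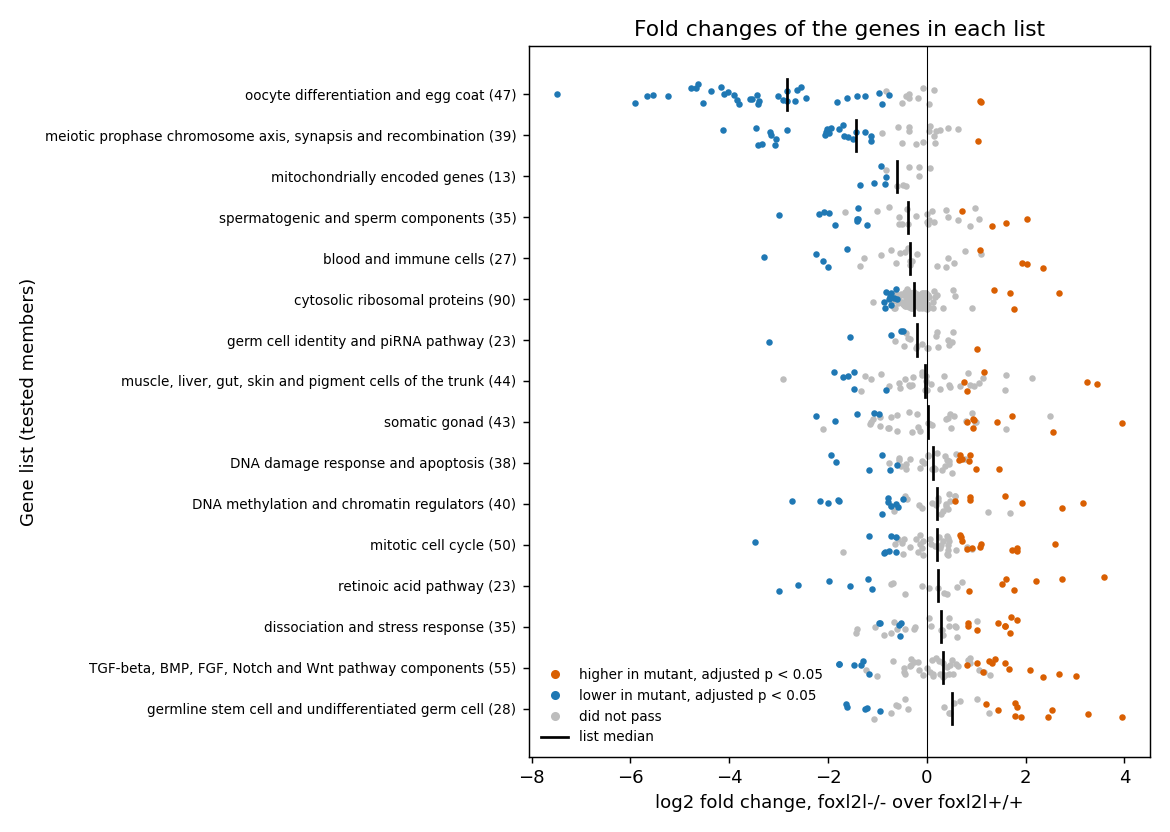
Log2 fold changes of foxl2l-/- over foxl2l+/+ cells for each tested member of the 16 gene lists, ordered by the list median (black bar). Orange and blue points passed the test as higher and lower, grey points did not, and the lowest medians are those of the oocyte list (-2.84) and the meiotic prophase list (-1.44).

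Pathway and regulator lists held changes in both directions. Of 55 components of the TGF-beta, BMP, FGF, Notch and Wnt pathways, 12 rose and 6 fell (likewise adjusted over the list alone), with a median of 0.33. Under library totals 13 rose and 4 fell, with a median of 0.54. Without foxl2l-/- replicate 3 the counts were 11 and 9, with a median of 0.26. The Hes-family repressor her9 rose by 2.34 ± 0.21 on the log2 scale (SE), the Notch ligand gene jag2b by 2.1 ± 0.29 and the Wnt target sp5l by 3.01 ± 0.49, while the receptor gene notch2 fell by 1.77 ± 0.24. In the retinoic acid pathway 7 of 23 genes rose and 6 fell (7 and 7 adjusted over the list alone). The retinol uptake receptor gene stra6 fell by 2.62 ± 0.23 and the retinol dehydrogenase gene rdh10b by 1.97 ± 0.20, while the retinaldehyde reductase genes dhrs3a and dhrs3b rose by 3.59 ± 0.55 and 1.61 ± 0.25. The median of that list was 0.22 and the mean 0.14, although camera ranked it lower, and the median was 0.42 under library totals and -0.10 without foxl2l-/- replicate 3. Of 40 DNA methylation and chromatin regulators, 12 fell and 7 rose (12 and 10 adjusted over the list alone). The histone demethylase gene kdm5ba fell by 2.16 ± 0.22 and the Polycomb gene pcgf6 by 1.81 ± 0.20, while hdac1 rose by 1.57 ± 0.17 and jarid2b by 3.16 ± 0.38. In the main scaling the median of these regulators was 0.21 and their mean 0.04 although camera ranked them lower. Under library totals 16 rose and 9 fell, with a median of 0.41, and without foxl2l-/- replicate 3 the counts were 5 and 11, with a median of 0.07.

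Of 50 mitotic cell cycle genes 11 rose and 8 fell (11 and 10 adjusted over the list alone), with a median of 0.21. Without foxl2l-/- replicate 3 the balance turned, with 7 higher, 11 lower and a median of 0.00, while under library totals 16 were higher and 6 lower, with a median of 0.42. The survivin gene birc5b fell by 3.47 ± 0.23 on the log2 scale (SE) and cdk2 by 1.16 ± 0.18, while the replication licensing gene cdt1 rose by 1.83 ± 0.20 and the spindle midzone gene prc1b by 1.82 ± 0.20. Of 38 DNA damage and apoptosis genes 7 rose and 6 fell (likewise adjusted over the list alone; 11 and 5 under library totals), with a median of 0.13 that became 0.33 under library totals and 0.05 without foxl2l-/- replicate 3. The p53 targets mdm2, bbc3 and gadd45aa fell by 1.94 ± 0.22, 1.84 ± 0.31 and 1.18 ± 0.25, and casp9 rose by 1.47 ± 0.24. Other p53 targets of the list, chosen after their values were seen, went both ways. Sesn1 rose (0.85) and ccng1 fell (-0.60), while cdkn1a (0.76) and pmaip1 (-0.11) did not pass. The camera adjusted p was 0.449 for the signalling list and 0.942 for each of the retinoic acid, chromatin, cell cycle and DNA damage lists.

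Markers of other cell types were scarce in all libraries and moved in both directions. Somatic gonad markers took 0.0344 ± 0.0035% of counts in foxl2l-/- and 0.0280 ± 0.0037% in foxl2l+/+ libraries, with every foxl2l-/- library above every foxl2l+/+ library (exact permutation p = 0.1, 0.26 after adjustment over the 13 composition measures). Of 43 tested, 8 rose and 5 fell (8 and 6 adjusted over the list alone; 8 and 3 under library totals), with a median of 0.03 that became 0.22 under library totals. The chemokine gene cxcl12a rose by 3.96 ± 0.60 on the log2 scale (SE) and the steroidogenic gene cyp17a1 by 1.72 ± 0.33, while emx2 fell by 2.24 ± 0.38 and col1a1b by 1.41 ± 0.27. Blood and immune markers took 0.0198% of counts in both genotypes. In that list 4 of 27 rose and 5 fell, likewise adjusted over the list alone, with a median of -0.34 (-0.15 under library totals, where 6 rose and 5 fell). The erythroid genes slc4a1a and alas2 fell by 2.25 ± 0.31 and 2.11 ± 0.32, and the leukocyte genes cd74b and ptprc rose by 2.02 ± 0.32 and 2.36 ± 0.42. Of 44 markers of muscle, liver, gut, skin and pigment cells, 5 rose and 6 fell (5 and 5 adjusted over the list alone), and their median of -0.03 and mean of 0.03 differed in sign. Under library totals 7 rose and 5 fell, with a median of 0.18, and without foxl2l-/- replicate 3 the counts were 6 and 5, with a median of 0.22. The muscle genes myl1 and tpma rose by 3.24 ± 0.35 and 1.15 ± 0.26, while atp2a1 fell by 1.47 ± 0.33 and the trypsin gene prss1 fell by 1.87 ± 0.40. The camera adjusted p was 0.942 for the somatic gonad and trunk lists and 0.837 for the blood list.

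Genes of dissociation and stress took 0.382 ± 0.0564% of counts in foxl2l-/- and 0.470 ± 0.0124% in foxl2l+/+ libraries (exact permutation p = 0.1, 0.26 after adjustment over the 13 composition measures). Of 35 such genes 9 rose and 5 fell (9 and 6 adjusted over the list alone), with a median of 0.29 and a camera adjusted p of 0.837. Under library totals 12 rose and 1 fell, with a median of 0.48, and without foxl2l-/- replicate 3 the counts were 5 and 4, with a median of 0.18. The immediate early genes junbb and egr2a rose by 1.83 ± 0.32 and 1.68 ± 0.41 on the log2 scale (SE), as did the mRNA decay factor zfp36l1a by 1.71 ± 0.33, and the chaperone gene hspa5 fell by 0.96 ± 0.20. In the ribosomal protein list, taken from symbols beginning with rps or rpl, 10 of 90 genes fell and 4 rose (2 and 4 adjusted over the list alone), with a median of -0.27 and a camera adjusted p of 0.0573. Under library totals 2 fell and 5 rose, with a median of -0.06, and without foxl2l-/- replicate 3 the counts were 2 and 6, with a median of -0.13. Of the members with the smallest p, rps6ka1, rps6ka3b and rps6kc1 (1.68 ± 0.22, 1.77 ± 0.32 and 1.37 ± 0.30) are kinase genes and rps19bp1 (-0.84 ± 0.17) encodes a binding protein, not ribosomal proteins. Of 13 mitochondrially encoded genes 5 fell and none rose (7 and 0 adjusted over the list alone), with a median of -0.60. These included mt-atp6 (-1.35 ± 0.26), mt-nd6 (-1.07 ± 0.28), mt-nd4 (-0.93 ± 0.23) and mt-atp8 (-0.85 ± 0.23). Both under library totals and without foxl2l-/- replicate 3, 4 fell, with a median of -0.40 each time. With edgeR's quasi-likelihood test the call of mt-nd6 ended without foxl2l+/+ replicate 2 (adjusted p = 0.0657, range 0.00241 to 0.0657 over the alternatives other than the 2-fold limit). That of mt-atp8 ended without foxl2l-/- replicate 2 (adjusted p = 0.0575, range 0.00213 to 0.0575 in the same way). The camera adjusted p of 0.0402 became 0.233 without foxl2l-/- replicate 3 and 0.109 without foxl2l+/+ replicate 2, with an adjusted p of 0.978 under an estimated correlation (0.00347 to 0.978 over the alternatives tried). Mitochondrial transcripts took 1.69% of counts in foxl2l-/- replicate 3 and 2.54% to 3.45% in the other libraries. No list of the 16 was called by camera with an estimated correlation.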

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

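Thinned counts and the ribosomal list restricted to ribosomal proteins were chosen after seeing the data. Across other scalings, tools and filters the count of 7443 called genes ranged from 7414 without a low-count filter to 9221 with limma-voom, with 8537 by DESeq2. On thinned counts it was 7354. It was 5401 with a 2-fold limit and lay between 5397 and 7055 when each library was left out. No called gene had the opposite sign under any of these settings. The share of higher calls was 49.8%, against 64.2% under library totals and 66.8% with limma-trend on TPM. With the replicate block 7199 genes were called, 6839 of them called without it. Same-numbered libraries did not deviate together (correlations of -0.0376, 0.0502 and 0.0366). The labels do not say that the numbers pair the libraries, and correlations near 0 cannot exclude a pairing.

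The measured foxl2l log2 fold change of 0.64 lies under a 2-fold limit, so that limit ended its call. It ranged from 0.488 to 0.799 with each library left out. Over the remaining alternatives its adjusted p ranged from 0.00206 to 0.0416 and the call was kept. Camera with an estimated correlation ended the calls of the meiotic (0.337), oocyte (0.373) and mitochondrial (0.978) lists, and fry that of the mitochondrial list (0.251). With each library left out the mitochondrial adjusted p ranged from 0.00347 to 0.233. Fry, which does not compare a list with other genes, called the stem cell list (0.0167) and the spermatogenic list (0.0142). Without foxl2l-/- replicate 3, 37 oocyte and 26 meiotic genes fell. The difference in detected genes was 194 at 1 count and 998 at 10 counts, and the cause was not tested. Restricted to 74 ribosomal protein genes, of which 9 fell and 0 rose, the ribosomal list had a camera adjusted p of 0.00779 (0.0573 for all 90) under the preset correlation. With an estimated correlation (0.951 for these 74) neither was called, with an adjusted p of 0.978 for each. The list of all 90 was called under 7 planned settings, and not under library totals (0.0044 to 0.978 over all alternatives, the 74-gene list included). Of 1393 values for the other 82 named genes, 1379 kept direction and side of the threshold and 14 lost the call. Of 194 values for the other 12 lists, 185 kept both and 9 gained a call. None of these reversed. The simulation recovered 21% of 2-fold changes with 200 genes changed, far fewer than the 7443 called here. Its adjusted threshold was therefore stricter, so the 21% does not measure recovery in these data. Genes that did not pass may still have changed.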

Other observations

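The interferon list and its tests were written after 7 of its genes had been seen, and the tests of scaling, depth, the share of oocyte-stage cells, linked variants and chromosome 4 were also chosen after the results they bear on were seen. Genes of the interferon response and of antigen processing were higher in foxl2l-/- cells. Of 63 tested 41 rose and 2 fell, isg20 (-0.75) and jak1 (-0.73), with a median log2 fold change of 1.48. Camera gave an unadjusted p of 4.48e-12, and 0.00146 with an estimated correlation. Neither can be set beside the adjusted p of the lists fixed beforehand. Unadjusted, camera with an estimated correlation gave p = 0.0467 for the oocyte list and 0.021 for the meiotic list. Members of the interferon list named here were chosen after their values were seen. Adjusted over the interferon list alone 43 rose and 2 fell. The ubiquitin-like gene isg15 rose by 2.98 on the log2 scale, from 97.8 ± 8.32 to 772 ± 146 CPM (SD, n = 3), and the MHC class I light chain gene b2m by 2.09, from 119 ± 14.2 to 508 ± 46.5 CPM. Among genes not seen beforehand, irf7 rose by 2.25, the immunoproteasome gene psmb8a by 2.03, the peptide transporter gene tap1 by 1.80 and stat1b by 2.58. Without the 7 genes seen first, 34 of 56 rose and 2 fell, with a median of 1.36. The unadjusted camera p was 1.95e-09, and 0.00365 with an estimated correlation. These 56 genes belong to the same responses as the 7 and come from the same libraries, so their rise is not independent support. Under library totals 43 of 63 rose and 1 fell.

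On chromosome 13, vent, the neighbour of vox, also rose by 3.65 on the log2 scale, from 1.89 ± 0.673 to 23.9 ± 3.39 CPM (SD, n = 3). The ligand gene bmp2b rose by 3.94, smad1 by 1.38, smad9 by 1.01 and the inhibitory smad6b by 1.25. The receptor genes bmpr1bb and bmpr2b rose by 1.66 and 1.59. All of id1, id2a, id2b, id3 and id4 rose, by 3.95, 1.45, 1.78, 1.79 and 2.45. These genes were picked because they rose, and were not tested as a list. Other BMP pathway members did not pass, among them smad5 (0.24), smad6a (-0.08), smad7 (0.41), bmpr1ab (0.13), bmpr1ba (-0.33), bmpr2a (0.11) and acvr1l (0.34), and the signalling list as a whole was not called (camera adjusted p = 0.449).

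The decrease of the oocyte list remained under other scaling and at equal depth. Neither check could have moved the list far. Mean TMM factors were 1.07 in foxl2l-/- and 0.932 in foxl2l+/+ libraries, and the smallest total was that of a foxl2l+/+ library. With library totals the oocyte list had a median of -2.64, and with every library thinned to the smallest total -2.87, against -2.84 as reported. A smaller share of oocyte-stage cells among the EGFP-positive cells could also lower these transcripts, and cannot be told apart from lower transcription per cell. A common dilution would lower all such genes alike, whereas the called members varied with an SD of 1.54 around a median SE of 0.317. That spread does not decide it, because each gene can have a level of its own in other germ cells.

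The interferon rise was weighed against leukocytes carried into the sort and against a single library. The 14 leukocyte markers had a median of -0.34, below the list's 1.48 by more than 2 standard errors of the difference (0.454 each). As a set they did not rise with the interferon list. All 14 belong to the blood and immune list above, so this comparison is not independent of that result. Its standard error treats genes as independent and does not measure the spread between libraries. Some markers lay near the floor, such as cd8a (0.795 CPM) and lcp1 (0.937 CPM) in foxl2l-/- cells. The comparison therefore does not decide whether leukocytes contributed. The single markers were split. Of the 4 most abundant in foxl2l-/- cells, ptprc (23.8 against 4.62 CPM) and cd74b (13.9 against 3.43 CPM) rose, while cd74a (26.3 against 18.1 CPM) and coro1a (13.3 against 16.8 CPM) did not pass, cd74a lying above foxl2l+/+ in every library. Rag2 and cd4-1 fell. Leukocytes of a kind rich in ptprc and cd74b are therefore not excluded. Without each foxl2l-/- library in turn the lowest median was 1.40, so no single foxl2l-/- library carries it. A difference in infection, clutch or tank between the genotypes was not tested, since the labels name none, and an effect of the genotype on these genes remains a hypothesis.

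Linked variants around the mutated locus would raise the share of called genes near foxl2l on chromosome 23. Within 5 Mb of it 34 of 195 genes rose and 26 fell (30.8% called), against 31.5% on the other chromosomes. The odds ratio was 0.966 (95% confidence interval 0.699 to 1.32, Fisher's exact p = 0.877). No excess of calls was seen near foxl2l, but the interval leaves room for a small one. The 195 genes could supply only a small part of the 7443 calls in any case, so this says nothing of most calls. On chromosome 4 from 30 Mb onward, 10.9% of 659 genes were called, against 32.2% elsewhere. Both directions were rarer there, with 2.73% rising and 8.19% falling against 16.1% each elsewhere. Among called genes, the ratio of falling to rising genes (54 to 18) was higher than elsewhere (3679 to 3692), with an odds ratio of 3.01 (95% interval 1.73 to 5.46, Fisher's exact p = 2.37e-05). Of the 659 genes 491 have clone names, and reads shared between similar copies there were not examined. Fisher's test, here and near foxl2l, counts genes as independent. Neighbouring genes measured in the same 6 libraries need not be, so its p-values and intervals do not measure the spread between libraries.

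The 6 libraries allow 10 splits into groups of 3, too few for a share under 0.05. By the same edgeR test the real split called 7443 genes and the highest of the others 0. The 1 split that reached the real count was the real split itself. Every other split mixed the genotypes, which places their difference in the spread within groups. The 0 calls there therefore do not tell genotype from any other difference between the 2 sets of libraries.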
